A study of Homo sapiens with 6 samples.

How the data were processed

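RNA of A375 cells, an established human melanoma line, was measured in 6 libraries, 3 of wildtype cells (WT) and 3 of cells overexpressing CYGB (CYGB-OE). Per the labels' protocols, the cells were untreated, RNA was purified on spin columns, messenger RNA was captured on oligo-dT beads, and cDNA was primed with random hexamers. The protocol text covers both strand-keeping and strand-blind library kits and does not say which was used, so reads of overlapping and antisense genes are uncertain. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2, with genome build GRCh38. The annotation and the strand setting of the counting are not given in the sources used here. No label says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels name no batch, no date and no empty-vector control.

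The deposited table gives raw counts per feature, per the file headers, with 1 column per library. It holds 2778 features, of which 2615 have an Ensembl gene identifier and 163 are unnamed loci. Of the identifiers, 2611 were found in GENCODE release 29, whose names, types and GRCh38 coordinates were used. The unnamed loci held 1.25% to 1.64% of the counts of a library. The authors' table was found to hold only part of the genes. With counts scaled within each group, the log2 ratios of the group means left an empty band 1.99 wide, from -1.07 to 0.92, and every feature lay outside it. A symmetric selection at 2-fold gives such a band, and its rule is not given in the sources used here. The column totals, 1533260 to 2801576 counts, are sums over the selected features and do not give the depth of a library. Genes outside the table were not analysed here, and no enrichment against a background of all expressed genes was computed.

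Groups were taken from the labels. The planned test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, two-sided, with filterByExpr (minimum count 10), TMM normalization, robust empirical Bayes and group as the only term, with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. One step departs from that plan and was chosen after the table was seen. TMM assumes that most features are unchanged, which a table of changed features does not meet. TMM factors were therefore computed within each group, and the level between the groups was set so that the middle of the empty band lies at a log2 ratio of 0. Against this scaling, TMM over the table raised all log2 fold changes by 1.2, DESeq2 size factors by 1.21, upper-quartile factors by 0.86 and total counts by 0.35. In 3 simulations of 12000 genes, only genes changed at least 2-fold either way on the simulated scale were kept. There the band's middle recovered the simulated level with errors between -0.000602 and 0.00112, and TMM was off by -1.05 to -1.11. That symmetric selection fixes the band's middle beforehand. The simulations therefore do not show that the authors' rule was symmetric or which level it was centred on. The planned TMM values are given beside the main counts. Normalized counts are counts divided by these factors, and values are given as mean ± SD over 3 libraries. Standard errors were derived from the F statistic. A common dispersion gave a biological coefficient of variation of 20.5%.

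Because features entered the table for a difference between these same libraries, a call here is not independent evidence of a difference, and adjusting over the table alone is lenient. Calls adjusted over all 58780 annotated genes, with the genes outside the table counted as not significant, were added as a stricter reading after the table was seen. Tests were checked on simulated counts for 2778 features, with 100 changed 2-fold and 100 changed 4-fold between CYGB-OE and WT. The edgeR test recovered 92% of the 2-fold and 100% of the 4-fold changes, with 8 false calls among 200. DESeq2 1.42.0 recovered 81% and 100%, and limma-voom (limma 3.58.1) 93% and 100%. Most simulated features were unchanged, their spread was set by a formula, and no simulated library stood apart. The table differs in these respects, so the rates do not give those of the calls here.

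Before the data were examined, 48 gene lists were fixed, covering redox, inflammatory, melanocyte, cell cycle, stress, signalling and matrix genes, and markers of other cell types. Lists with at least 5 tested members, 17 in all, were compared with the other features of the table by limma's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, and again with an estimated correlation. The directional rotation test fry was run beside it; it asks whether the genes of a list move one way on balance and compares them with no other genes. On simulated counts, camera with the preset correlation and fry each called the 1 raised list and 0 of 40 unchanged lists. The simulated genes were independent and mostly unchanged, unlike those of the table, so these counts do not give the rate of false list calls here. Member counts past the threshold are given over all features tested and adjusted over the list alone.

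The rule for named genes was also fixed before the data were examined. It takes CYGB; the 12 genes with the largest and the 12 with the smallest log2 fold change among those past the threshold with at least 5 CPM in the higher group and no overlap between groups, leaving out unnamed, clone, long non-coding and pseudogene names and sex-linked markers; and, for each list described, up to 4 members with the smallest adjusted p. CPM here is taken over the counts of the table. Protein-coding genes with a mean normalized count of at least 1000 and the 12 largest or smallest log2 fold changes were added after the values were seen, as were the genes of the closing section. A gene that the rule takes is not reported here.

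Where a group had no count, a fold is given as a bound against 3 counts over the group, and where it had 1 to 3 counts, as a ratio with a 95% exact binomial interval, also where a library was left out. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared before averaging. The chi-square per degree of freedom between libraries of a group ran from 3.75 to 35.3, so no pair agreed within sampling noise. Alternatives planned before the data were examined were the normalizations above, DESeq2 with its own size factors, limma-voom, no filter, a filter of 1 CPM in 3 libraries, no robust estimation, a replicate block, a test against a fold of 1.2, and leaving out each library in turn. DESeq2 and limma-voom with the band-centred scaling, and the table without the unnamed loci, were added after it was seen. Computation used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.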

Results

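The RNA of A375 cells, a human melanoma line, was compared between wildtype cells (WT, n = 3 libraries) and cells overexpressing CYGB (CYGB-OE, n = 3 libraries). CYGB encodes cytoglobin, a haem protein of the globin family. The series asks which transcripts differ between these groups. The deposited table holds counts for 2778 features, with totals of 2025159, 2801576 and 2078819 counts in WT replicates 1 to 3 and 1688254, 1533260 and 1897052 in CYGB-OE replicates 1 to 3. No feature had a log2 ratio of group means between -0.995 and 0.995, so the table is a selection of features that differed about 2-fold or more between these libraries. The totals are therefore not library depths, and statements below cover the listed features only. CYGB-OE replicate 1 stood apart: its features differed from replicates 2 and 3 by a median of 0.364 and 0.346 log2 units, against 0.109 between replicates 2 and 3 and 0.096 to 0.11 among the WT libraries.

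CYGB was the first gene examined, as a check of the labels. CYGB (ENSG00000161544, GRCh38 chromosome 17, 76527356 to 76551175) had 33, 47 and 37 counts in the WT libraries and 22518, 20740 and 26267 in the CYGB-OE libraries. Its normalized count rose from 37.6 ± 1.56 in WT to 23680 ± 460 in CYGB-OE (SD, n = 3 each). The log2 fold change was 9.30 (SE 0.11; edgeR quasi-likelihood test, adjusted p = 1.78e-10), and every CYGB-OE library lay above every WT library. The annotation places PRCD on the opposite strand over the same region, so with an unknown strand setting some WT reads may belong to PRCD. The CYGB level was alike in the 3 CYGB-OE libraries, at normalized counts of 24020, 23160 and 23870.

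Among genes higher in CYGB-OE, matrix metalloproteinases had some of the largest folds. MMP1, the interstitial collagenase, rose from 198 ± 9.79 to 4062 ± 655 normalized counts (log2 fold change 4.36, SE 0.15; edgeR adjusted p = 4.72e-07). MMP3 and MMP10, the stromelysins, had log2 fold changes of 6.49 and 5.29. CACNA1E, a voltage-gated calcium channel subunit, rose from 2.34 ± 0.88 to 268 ± 141 normalized counts (log2 fold change 6.82), and COL1A2, a chain of type I collagen, had a log2 fold change of 5.91. UTS2, which encodes the peptide urotensin 2, rose from 19.4 ± 6.62 to 745 ± 52.3, with a log2 fold change of 5.22 (SE 0.22; edgeR adjusted p = 9.46e-07). The log2 fold change was 6.18 for NTS, the neurotensin gene, 5.21 for the integrin ITGA8, 5.00 for the tubulin TUBB1 and 4.96 for the annexin ANXA10. LRRC53 and SERTM2 had 0 counts in the WT libraries and were at least 17-fold and 15.6-fold higher in CYGB-OE (10.1-fold and 9.25-fold without WT replicate 2). Of these, NTS, MMP10 and ANXA10 were set in large part by CYGB-OE replicate 1, without which their log2 fold changes were 4.64, 4.09 and 3.62. NTS and ANXA10 lost their calls when adjusted over all annotated genes. Without WT replicate 2, WT held 1 count of MMP3 and 2 of COL1A2, and CYGB-OE exceeded WT 286-fold (95% interval 51.1 to 11300) and 114-fold (31.5 to 949).

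Among more abundant protein-coding genes that were higher in CYGB-OE, RGS2, a regulator of G-protein signalling, rose from 558 ± 227 to 4255 ± 1205 normalized counts (log2 fold change 2.93). The homeobox transcription factor PRRX1 rose from 3389 ± 290 to 13710 ± 1925 (log2 fold change 2.02, SE 0.13; edgeR adjusted p = 4.61e-06), and MEIS2, another homeobox gene, had a log2 fold change of 1.57. MYH15, NPTX2, NEFL, VAT1L, SLITRK6, AEN and NCOA5 had log2 fold changes of 2.02, 1.80, 1.68, 1.67, 1.67, 1.64 and 1.63. These genes were chosen for abundance after their values were seen.

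Among genes lower in CYGB-OE, those of interleukin 1 had some of the largest folds. IL1B fell from 1290 ± 59.4 to 6.43 ± 9.28 normalized counts (log2 fold change -7.67, SE 0.66; edgeR adjusted p = 4.98e-05), and IL1A from 8734 ± 252 to 171 ± 190 (log2 fold change -5.68). The log2 fold change was -6.29 for ST8SIA1, the sialyltransferase that makes ganglioside GD3, -6.20 for ZP4, -6.19 for the ETS factor ELF3, -6.15 for the cadherin FAT3, -5.87 for COL22A1 and -5.43 for the integrin ITGAM. ASB11 had 0 counts in the CYGB-OE libraries and was at least 25.7-fold lower (16.1-fold without CYGB-OE replicate 3). REM1, MYOCD and NXF2 had at most 3 counts there; WT exceeded CYGB-OE 180-fold for REM1 (95% interval 31.9 to 7140), 80.0-fold for MYOCD (14 to 3200) and 71.6-fold for NXF2 (12.5 to 2860), and NXF2 has a near-identical copy that makes its count uncertain. Several of these genes were less low in CYGB-OE replicate 1. Without that library the log2 fold changes were -7.14 for IL1A and -7.78 for ELF3. CYGB-OE then held 2 counts each of IL1B, ZP4 and ST8SIA1, and WT exceeded it 1280-fold (95% interval 354 to 10600), 663-fold (183 to 5480) and 228-fold (63.0 to 1890). It held 0 counts of COL22A1, ITGAM, REM1 and MYOCD, which were at least 98.2-fold, 61.5-fold, 40.8-fold and 18.2-fold lower. Leaving out CYGB-OE replicate 2 gave -7.08 for FAT3 and left NXF2 at 0 counts, at least 16.6-fold lower. Leaving out replicate 3 gave -7.02 for IL1B, -5.23 for COL22A1 and -4.79 for ITGAM, and ratios of 112 for REM1 (19.9 to 4460), 50 for MYOCD (8.74 to 2000) and 44.7 for NXF2 (7.79 to 1790).

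Abundant protein-coding genes also fell by large folds. TXNIP, an inhibitor of thioredoxin and of glucose uptake, fell from 27670 ± 2200 to 782 ± 164 normalized counts (log2 fold change -5.14, SE 0.18; edgeR adjusted p = 4.72e-07). SULF1, a heparan sulfate endosulfatase, fell from 4135 ± 176 to 108 ± 63.4 (log2 fold change -5.26), and the transcription factor CEBPD from 6261 ± 624 to 464 ± 87.9 (log2 fold change -3.76). SOD2, the mitochondrial manganese superoxide dismutase, had a log2 fold change of -3.98, complement C3 of -3.17, the adhesion molecule ICAM1 of -2.82, the cytokine subunit EBI3 of -3.90 and phospholipase PLD1 of -2.79. Without CYGB-OE replicate 1, the log2 fold change was -4.40 for C3, -3.70 for ICAM1 and -4.67 for EBI3. Adjusted over all annotated genes, C3 and ICAM1 lost their calls.

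**Figure D1:**
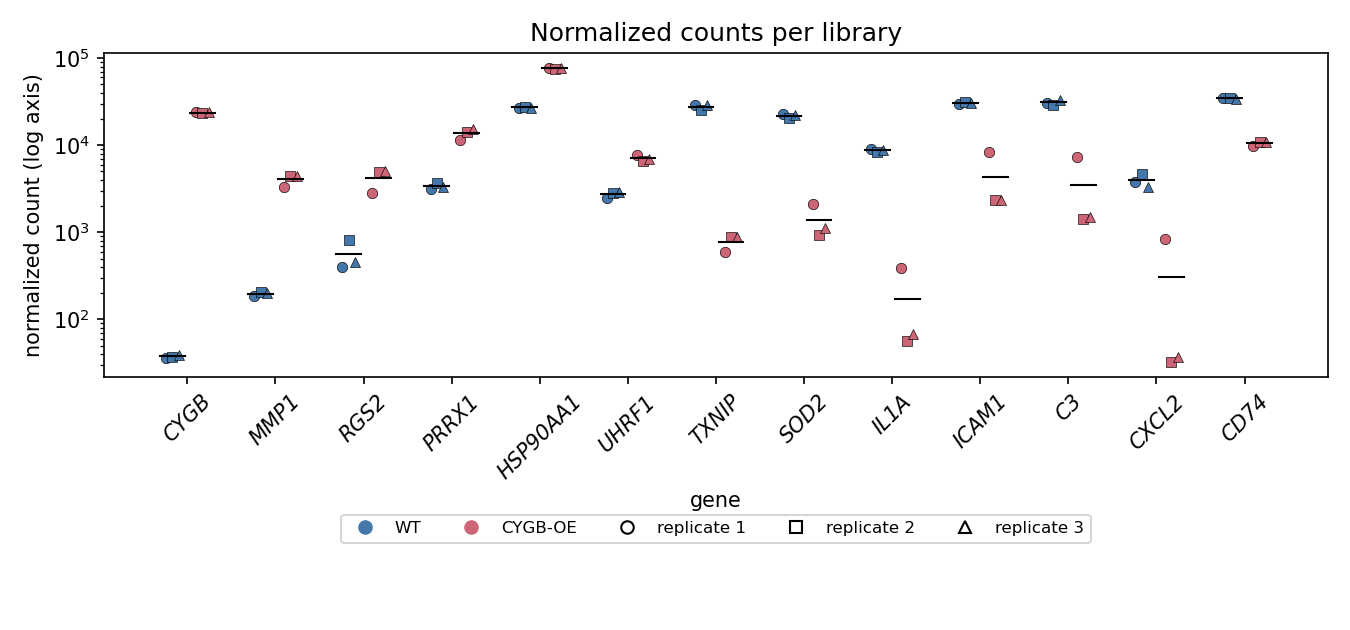
Normalized count of 13 named genes (vertical log axis) in each library, WT in blue and CYGB-OE in red, with the replicate shown by the symbol and the group mean by a bar. CYGB lies near 23680 in all 3 CYGB-OE libraries, while ICAM1, C3, IL1A and CXCL2 are higher in CYGB-OE replicate 1 than in replicates 2 and 3.

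Of 2468 features tested, 713 were higher and 1749 lower in CYGB-OE (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted, threshold 0.05), of which 707 and 1749 differed at least 2-fold. The share of lower calls was 71.0%, so a list of genes from this table is mostly lower without any trait of its own. By annotation, 672 named genes and 41 unnamed loci were higher, and 1649 and 100 were lower. Only 6 of the tested features did not pass the threshold. Passing when adjusted over a list alone therefore follows from the selection and adds no support to the lists below. In 2732 of the 2778 features the groups did not overlap, against 10% by chance for 3 against 3 libraries, but features were selected for such differences. With the planned TMM scaling over the table, 714 were higher and 480 lower, because that scaling raises all log2 fold changes by 1.2 and turns 385 lower calls with smaller folds positive. Under it 24 of the genes named here or in the closing section lost their call and 4 changed sign. Adjusted over all annotated genes, 479 were higher and 1340 lower. Without CYGB-OE replicate 1, 730 were higher and 1837 lower.

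Genes of NF-kB signalling and inflammatory cytokines were mostly lower in CYGB-OE. Of 35 genes on the list, 18 were in the table and 17 were tested, of which 15 fell and 2 rose, and the counts adjusted over the list alone were the same 15 and 2. Adjusted over all annotated genes, ICAM1, NFKBIA and CXCL2 lost their calls. So did the other lower members with a larger adjusted p than ICAM1 (edgeR adjusted p = 0.00334 over the table). The 2 that rose were the metalloproteinases MMP1 and MMP3. NFKBIA, which encodes the NF-kB inhibitor IkB-alpha, fell from 8833 ± 117 to 1246 ± 1149 normalized counts (log2 fold change -2.83), TRAF1 had a log2 fold change of -3.14, and CSF1, a macrophage growth factor, of -1.42. The chemokine CXCL2 fell from 3942 ± 694 to 306 ± 470 (log2 fold change -3.69, edgeR adjusted p = 0.0415). The list's median log2 fold change was -2.52. Against the other features of the table the list was not called (camera adjusted p = 0.439, or 0.884 with an estimated correlation). That does not show the list to be like them, since the comparison includes MMP3 and MMP1, at log2 fold changes of 6.49 and 4.36. The list's genes moved downward on balance (fry adjusted p = 0.0123). In this table of selected features 15 of the 17 lists passed fry, so that call was nearly assured. The fall was smaller in CYGB-OE replicate 1: without it the median was -3.35, with 2 higher and 16 lower, and the log2 fold changes of NFKBIA and CXCL2 were -3.92 and -6.81. The CXCL2 call was lost without WT replicate 1, 2 or 3 or CYGB-OE replicate 3 (edgeR adjusted p = 0.0551, 0.0632, 0.0723 and 0.0588), and under TMM scaling 7 of the 15 stayed lower past the threshold while all 15 stayed below 0.

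Of 24 inflammasome and pyroptosis genes, 9 were in the table and 8 were tested; all 8 fell, also when adjusted over the list alone (median log2 fold change -2.64). They include TXNIP, IL1A and IL1B. P2RX7, an ATP-gated ion channel, fell from 426 ± 44.3 to 35.1 ± 6.51 normalized counts (log2 fold change -3.59), NLRP1, an inflammasome sensor, had a log2 fold change of -1.68 and NINJ1, which acts in membrane rupture, of -1.44. Camera gave an adjusted p of 0.102, or 0.558 with an estimated correlation, and under TMM scaling 5 were lower past the threshold and 6 of the 8 stayed below 0. Without WT replicate 1, CYGB-OE replicate 1 or CYGB-OE replicate 3, all 9 in the table passed the filter and fell, with medians of -3.56, -3.46 and -3.74 (-3.43 for the last with low counts at their bound).

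Matrix proteases were mostly higher. Of 37 genes on a list of matrix proteases and inhibitors, 8 were in the table, all of them proteases; 6 rose and 2 fell, also when adjusted over the list alone, with a median log2 fold change of 2.38. Under TMM over the table, which raises all folds, the 6 stayed higher, 0 were lower past the threshold and 1 of the 2 stayed below 0. Beside the metalloproteinases, the aggrecanases ADAMTS5 and ADAMTS4 had log2 fold changes of 3.05 and 1.63. Against the other features of the table the list stood higher (camera adjusted p = 0.00588, or 0.443 with an estimated correlation). Every other split of the libraries into 3 and 3 also gave 3 or more lists past camera's threshold. This limits the call and those of the G1/S and histone lists below.

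Genes of the G1/S transition and of DNA replication were higher in CYGB-OE: 8 of 41 on the list were in the table and all 8 rose, also when adjusted over the list alone, with a median log2 fold change of 1.21. UHRF1, which maintains DNA methylation at replication, rose from 2743 ± 207 to 7107 ± 517 normalized counts (log2 fold change 1.37). PCNA, the replication clamp, had a log2 fold change of 1.24, the replication initiation factor MCM10 of 1.18 and the phosphatase CDC25A of 1.03. Camera gave an adjusted p of 0.000124 with the preset correlation, but the call was lost at an adjusted p = 0.578 with an estimated correlation. None of 44 G2/M genes and none of 34 DNA repair genes were in the table, so their changes were not analysed here.

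Replication-dependent histone genes rose in 6 of 6 tested of 36 on the list, also when adjusted over the list alone (median log2 fold change 1.43). HIST1H2BC, HIST1H2AC and HIST1H2BJ had log2 fold changes of 1.66, 1.17 and 1.13. Their sequences are near-identical to other histone genes, and transcripts of this class mostly lack a poly(A) tail. Poly(A)-selected counts of them are therefore uncertain. Adjusted over all annotated genes, HIST1H2BC and HIST1H2BJ lost their calls (adjusted p = 0.0569 and 0.0802). So did the listed histone genes with edgeR adjusted p = 0.00699 and 0.00844 over the table, which lie above that of HIST1H2BJ (0.00337). The list stood above the other features (camera adjusted p = 0.00588; adjusted p = 0.443 with an estimated correlation). All 4 heat shock genes in the table rose, also when adjusted over the list alone: HSP90AA1 went from 27280 ± 383 to 76710 ± 1140 normalized counts (log2 fold change 1.49), and HSPH1, HSPE1 and BAG3 had log2 fold changes of 1.46, 1.16 and 1.04.

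Of 45 collagen and matrix genes, 16 were in the table and 14 were tested; 3 rose and 11 fell, also when adjusted over the list alone, with a median log2 fold change of -1.18 that became 0.02 under TMM over the table, where 3 were higher and 2 lower past the threshold and 7 of the 11 stayed below 0. COL16A1, HSPG2 (perlecan) and COL12A1 had log2 fold changes of -1.65, -1.46 and -1.21. LAMA5, a laminin chain, had -1.10, which turned to 0.10 under TMM over the table. Camera gave an adjusted p of 0.675, or 0.881 with an estimated correlation.

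All 6 tested melanocyte genes of 30 on the list fell, also when adjusted over the list alone (median log2 fold change -1.46; camera adjusted p = 0.306, or 0.854 with an estimated correlation). EDNRB, the endothelin receptor of melanocytes, fell from 1804 ± 93.0 to 637 ± 57.9 normalized counts (log2 fold change -1.50), and RAB38, which acts in melanosome transport, had a log2 fold change of -1.42. S100A1 had -1.11, which turned to 0.09 under TMM over the table. Under that scaling 1 of the 6 stayed lower past the threshold and 4 stayed below 0.

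Genes of antigen presentation and the interferon response were mostly lower, as was the table as a whole (71.0% of calls). All 3 listed MHC class II genes in the table fell, and all 4 MHC class I genes, also when adjusted over each list alone. CD74, the invariant chain, fell from 34610 ± 279 to 10510 ± 517 normalized counts (log2 fold change -1.72, SE 0.08; edgeR adjusted p = 9.46e-07), and CIITA, the class II transactivator, and HLA-DPB1 had log2 fold changes of -1.32 and -1.52. Of 7 type I interferon genes tested, 1 rose and 6 fell, also when adjusted over the list alone (median log2 fold change -1.27; camera adjusted p = 0.646, or 0.880 with an estimated correlation). The RNA sensor IFIH1 had a log2 fold change of -1.52, TRIM22 of -1.29 and IFITM1 of -1.27, and DDX58 had -1.19, which turned to 0.01 under TMM over the table. Under that scaling 4 of the 6 lower interferon genes stayed below 0 and 0 past the threshold. Of the class II genes 3 stayed below 0 and of the class I genes 3 of 4, with 1 of each lower past the threshold.

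Redox genes moved both ways. Of 5 antioxidant enzymes tested, 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.306, or 0.578 with an estimated correlation). PRDX1, a peroxiredoxin, rose from 9456 ± 224 to 21130 ± 827 normalized counts (log2 fold change 1.16), GLRX2 had a log2 fold change of 1.06 and the secreted peroxidase GPX3 of 1.66, while SOD2 fell. Both NRF2 targets in the table rose, GCLM of glutathione synthesis (log2 fold change 1.12) and the cystine transporter SLC7A11 (1.03). The 2 tested NADPH oxidase genes fell: NOXA1 had a log2 fold change of -2.83, and NOX4, which makes hydrogen peroxide, fell from 306 ± 16.6 to 55.3 ± 22.1 normalized counts (-2.46). Of 4 ferroptosis genes 2 rose and 2 fell, with SAT1 at a log2 fold change of -2.44 and the transferrin receptor TFRC at 1.46. Of 4 nitric oxide and cGMP genes 2 rose and 2 fell. NOS1, the neuronal nitric oxide synthase, had a log2 fold change of 3.06 (3.71 without WT replicate 3), the cytochrome b5 gene CYB5B of 0.9998, the arginine-recycling enzyme ASS1 of -1.56 and the cGMP-dependent kinase PRKG1 of -1.43. NOS1 lost its call when adjusted over all annotated genes. TFRC and CYGB were the 2 members of the globin and haem list in the table. Under TMM over the table, 1 antioxidant enzyme, 2 NADPH oxidase and 2 ferroptosis genes stayed lower past the threshold. ASS1 and PRKG1 lost their calls (log2 fold changes -0.36 and -0.23), which left 2 higher and 0 lower nitric oxide and cGMP genes.

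Of 5 hypoxia targets tested, 1 rose and 4 fell, also when adjusted over the list alone (median log2 fold change -1.77; camera adjusted p = 0.821, or 0.884 with an estimated correlation). HILPDA, ADM and NDRG1 had log2 fold changes of -1.94, -1.77 and -2.10, the last -2.77 without CYGB-OE replicate 1, while the glucose transporter SLC2A1 had 1.02. Of the glycolysis list, SLC2A1 rose and ALDOC and ENO2 fell (-1.47 and -1.42). All 5 tested apoptosis regulators fell, also when adjusted over the list alone (median log2 fold change -1.50; camera adjusted p = 0.306, or 0.880 with an estimated correlation). They comprise the pro-apoptotic BMF (-2.22), BBC3 (-1.50) and BOK (-1.29) as well as the anti-apoptotic BCL2A1 (-3.57, or -5.36 without CYGB-OE replicate 1). Under TMM over the table, 1 hypoxia target and 2 apoptosis regulators stayed lower past the threshold, and ALDOC and ENO2 lost their calls (-0.27 and -0.22). ENO2 also lost its call when adjusted over all annotated genes (adjusted p = 0.0899), and so did NDRG1.

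**Figure D2:**
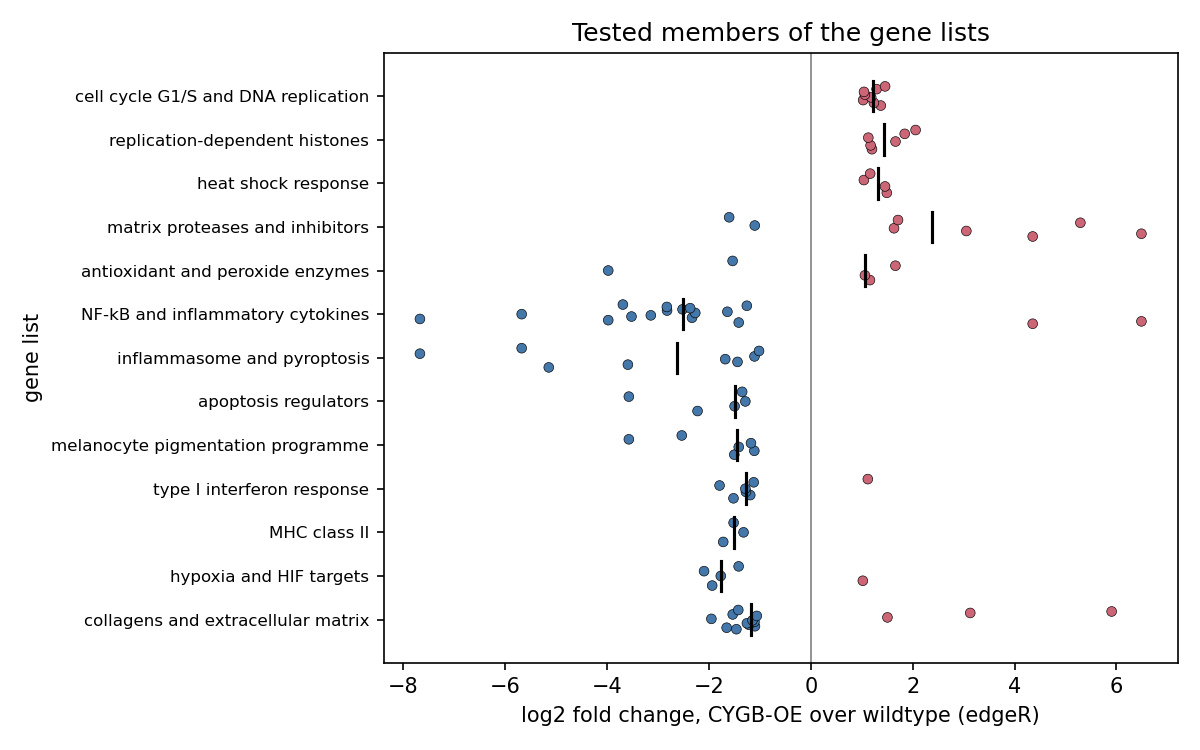
Log2 fold change, CYGB-OE over WT (horizontal axis), of each tested member of 13 gene lists (vertical axis); each point is a gene, red above 0 and blue below 0, and the bar is the list's median. All members of the G1/S, histone and heat shock lists lie above 0, and 15 of 17 NF-kB members lie below 0; the TMM scaling over the table would move every point right by 1.2.

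The other signalling and stress lists moved both ways or held few listed genes, with the same counts adjusted over each list alone. Higher and lower members numbered 2 and 6 for WNT, 1 and 5 for NOTCH, 1 and 4 for TGF-beta and BMP, 2 and 4 for semaphorins and axon guidance, 3 and 4 for ATF4 and amino acid stress, and 3 and 3 for dedifferentiated melanoma. Under TMM over the table the lower members past the threshold numbered 2, 1, 0, 0, 0 and 0 in that order, and 5, 3, 3, 3, 3 and 1 stayed below 0. Camera gave adjusted p from 0.477 to 0.843 for these lists, and from 0.854 to 0.884 with an estimated correlation. Lists with fewer members were not tested as sets. They had 1 and 3 for p53 targets, 0 and 4 for epithelial-mesenchymal genes, 2 and 2 for YAP/TAZ targets, 1 and 2 for MAPK output, 1 and 1 for immediate early genes, 0 and 3 for cancer-testis antigens, 1 and 3 for ABC transporters, 1 and 2 for cytosolic ribosomal proteins, 2 and 0 for mitochondrially encoded genes, and 0 and 2 for fatty acid synthesis. Under TMM the lower members past the threshold were 1 each for epithelial-mesenchymal genes, cancer-testis antigens and ribosomal proteins and 0 for the others. Of the lower members, 2 of 3 p53 targets, 1 of 2 MAPK, 2 of 3 cancer-testis, 1 of 3 ABC transporter and 1 of 2 ribosomal genes stayed below 0, and all those of the other lists did. Oxidative phosphorylation, cholesterol synthesis, unfolded protein response, nuclear-retained RNAs and melanoma suppressors had 1 listed gene each, which was lower. Under TMM over the table the first 2 turned to 0.12 and 0.17, the next 2 lost their calls at -0.07 and -0.08, and the last stayed lower. CTGF, of 3 of these lists, and CYR61, also of 3, had log2 fold changes of 1.2 and 1.02. Without CYGB-OE replicate 1 neither passed the threshold (edgeR adjusted p = 0.099 and 0.103), at log2 fold changes of 1.21 and 1.15 that were no smaller. The higher members past it then numbered 1 for dedifferentiated melanoma and 0 for TGF-beta, YAP/TAZ and immediate early genes. Of the lower members, 2 p53 targets passed without WT replicate 3 or CYGB-OE replicate 2, and 1 ribosomal gene without CYGB-OE replicate 1. CYR61 also lost its call without WT replicate 1 or 3 or CYGB-OE replicate 2 or 3 (edgeR adjusted p = 0.0626, 0.0574, 0.0522 and 0.0635). Over the 46 lists with a tested member, 14 medians changed sign under at least 1 of the other scalings. Each list kept its number of higher members under all 4 of them. All 4 raise the log2 fold changes, so that was nearly assured, and no scaling that lowers them was run.

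Markers of other cell types did not move together, with the same calls adjusted over each list alone. Of leukocyte markers, LYZ and LAPTM5 had log2 fold changes of 2.49 and 1.09 and ITGAM of -5.43. Of fibroblast markers, COL1A2 and PRRX1 rose and ACTA2 fell (-2.01). The endothelial markers KDR and TIE1 fell (-3.56 and -2.05), 1 of them past the threshold under TMM over the table. The keratinocyte markers SFN and KRT14 rose (2.06 and 1.88) and DSC3 fell (-1.13), which turned to 0.07 under TMM over the table. LIN28B (1.55) and NEFL, listed for packaging lines, rose, while PAX2 of the same list had 17.1 ± 6.64 normalized counts in WT and 4.56 ± 2.0 in CYGB-OE. PAX2 was not tested with all 6 libraries, as it did not pass the count filter, and was called lower without CYGB-OE replicate 1 (log2 fold change -1.85). The list also had 1 lower gene without WT replicate 2, CYGB-OE replicate 2 or CYGB-OE replicate 3. The fibroblast marker COL3A1 (0.63 ± 0.567 and 17.1 ± 13.7) and the keratinocyte marker DSG1 (12.9 ± 6.07 and 2.20 ± 2.23) were not tested with all 6 libraries either, and fibroblast markers had 3 higher, with COL3A1, without CYGB-OE replicate 1 or any 1 WT library.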

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

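The tests chosen after the data were seen are the band-centred scaling itself, its use with DESeq2 and limma-voom, the table without unnamed loci, the adjustment over all annotated genes and, for CYGB and the 2-fold counts, the test against a fold of 1.2. CYGB stayed higher past the threshold in every alternative run, with a log2 fold change of 9.27 to 9.33 when 1 library was left out. The counts of higher genes stayed within 1.5 times in every alternative run. The other scalings all raise the folds, so for them this was nearly assured. The counts that moved further did so with the scaling between groups, which by construction shifts all folds alike. Lower genes numbered 480 with TMM over the table, 476 with DESeq2 size factors in edgeR, 910 with upper-quartile factors, 503 with DESeq2 and its own size factors and 514 with limma-voom and TMM, against 1749. At least 2-fold lower were 321, 318, 541, 352 and 343 in the same order, and 1134 with total counts only. The lists past camera's threshold numbered 5 with TMM, with DESeq2 size factors, with DESeq2 and with limma-voom on TMM, against 3; the cause was not tested. With an estimated correlation, 0 lists passed camera (3 with the preset correlation), and 15 passed fry, which asks a different question.

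Log2 fold changes that reversed did so under the same shift. With TMM over the table, DESeq2 size factors in edgeR, DESeq2 with its own factors and limma-voom with TMM they were 0.103, 0.109, 0.109 and 0.106 for LAMA5; 0.090, 0.098, 0.098 and 0.085 for S100A1; 0.010, 0.019, 0.018 and 0.006 for DDX58; and 0.074, 0.085, 0.086 and 0.016 for DSC3. Among the named genes, 24, 23, 21 and 17 lost their call under these 4 settings, 7 with upper-quartile factors and 14 when adjusted over all annotated genes, namely CXCL2, CTGF, CYR61, C3, NFKBIA, ICAM1, NTS, ANXA10, HIST1H2BC, HIST1H2BJ, NOS1, NDRG1, ENO2 and INHBA. CXCL2 also lost its call without a filter, with a filter of 1 CPM, with total counts and without the unnamed loci.

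With 1 library left out, 708 to 751 genes were higher and 1761 to 1840 lower, 629 to 733 and 1673 to 1788 of them at least 2-fold, and 3 to 4 lists passed. Of the named genes, CXCL2, CTGF and CYR61 lost their call in 1 or more of these fits. Same-numbered libraries did not deviate together (correlations 0.022, -0.016 and 0.013 over 1114 features), and the replicate block gave 712 higher and 1750 lower, sharing 2459 of 2462 calls and changing no call of a named gene. DESeq2 with the band-centred scaling called all 2778 features, 2773 of them at 2-fold or more. Sequencing depth is unknown, since the table holds selected features, so no limit of detection can be given for genes outside it.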

Other observations

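The tests of this part were chosen after the results were seen, except those of abundance and of host genes for the short and intronic RNAs. The tests of mixed-in wildtype RNA, of library scaling and of histone genes were also revised after a first version had been run. Among genes not described so far, and chosen after their values were seen, ARRDC4, an arrestin-domain relative of TXNIP, fell from 1488 ± 45.6 to 216 ± 31.7 normalized counts in CYGB-OE (log2 fold change -2.78; edgeR adjusted p = 1.37e-06). CSPG4, the melanoma proteoglycan NG2, fell from 53780 ± 2454 to 14610 ± 799 (log2 fold change -1.88), and the matrix link protein HAPLN1 from 12550 ± 466 to 2766 ± 267 (log2 fold change -2.18). The lysyl oxidase LOXL4 had a log2 fold change of -2.09, the guanylate-binding protein GBP2 of -2.56, the tumour suppressor gene CDKN2A of -2.07 and INHBA, an activin subunit, of -2.37, or -3.13 without CYGB-OE replicate 1. The actin gene ACTB rose from 39420 ± 2856 to 98230 ± 3745 normalized counts (log2 fold change 1.32), TUBA1B had a log2 fold change of 1.14 and HNRNPA2B1 of 1.05. ST6GALNAC2, which lies near CYGB on chromosome 17, fell from 37.1 ± 6.44 to 2.75 ± 1.70 (log2 fold change -3.71).

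The lower level of NF-kB and inflammatory cytokine genes in CYGB-OE was weighed against scaling and against single libraries. Leaving out 1 CYGB-OE library left at least 14 of the 15 lower genes past the threshold, so these calls did not rest on 1 CYGB-OE library. The 15 were taken as already past it, in a table selected for this difference. Their staying past it was nearly assured and is no evidence about the cause of the fall. Between-group scaling stays open as a partial source: with the TMM scaling, 7 of the 15 stayed past the threshold, as the median log2 fold change of the 15 moved to -1.62 while all 15 stayed below 0. Clone or culture differences between the 2 groups may contribute and were not tested, since the labels name no clones and no vector control.

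Within CYGB-OE, the same 15 genes were all higher in replicate 1 than in the mean of replicates 2 and 3, by a median log2 ratio of 1.75. CXCL2 had normalized counts of 849, 32.4 and 37.3, NFKBIA of 2573, 595 and 569, and ICAM1 of 8275, 2335 and 2354. None of 10000 random lists matched on mean count reached that median (highest 0.831), a description of these libraries only. Scaling of that library does not account for it, since 1 factor moves all its genes alike. The median of the 15 exceeded that of 10000 random lists of other lower genes matched on mean count by 1.65, and none of those lists reached it (highest 1.18). Wildtype RNA or cells mixed into that library would lift all lower genes alike, but the share of wildtype RNA needed had a median of 1.03% over 594 other lower genes (quartiles -9.25% to 14.1%) against 20.8% over the 15 (lower quartile 7.87%). In replicate 1, 19 of the 594 stood under 7.87% of their WT level, TXNIP at 2.14%, which limits the share. Less CYGB mRNA in that library is also not seen, as its log2 ratio over the other CYGB-OE libraries was 0.031. A difference in culture state, such as NF-kB activity at harvest, may remain as a hypothesis that the labels give no way to test.

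Of sense-intronic RNA, snoRNA and microRNA genes, 34 of 43 called were higher (79.1%, 95% exact interval 64.0% to 90.0%), against 447 of 1653 protein-coding genes (27.0%; Fisher's exact test, two-sided p = 3.84e-12, across genes, which are not independent). By class, 13 of 13 snoRNA, 6 of 7 microRNA and 15 of 23 sense-intronic genes were higher. The 3 classes were chosen after their values were seen, so the p above decides nothing about whether they differ, and sense-overlapping RNA (4 higher, 2 lower) and processed pseudogenes (23 and 16) were also more often higher than lower. Low abundance does not account for it, as 28.2% of protein-coding features matched on mean count were higher. Host genes that rose stay open: 33 of the 34 lie inside a same-strand host gene, and 2 of the 34 (5.88%) have a host that is in the table and higher. The bound set beforehand for this share cannot exclude them, since for 30 of the 33 no host is in the table, which leaves those hosts without a value. Different recovery of RNA without a poly(A) tail between the groups may be a source and stays open. The 6 replication-dependent histone genes past the threshold, of a class whose transcripts mostly lack that tail, were all 6 higher. After oligo-dT capture, the counts do not show whether the reads of these 6 came from transcripts with or without a tail. Their rise is therefore no measure of such recovery. All 8 tested G1/S and DNA replication genes rose as well, so the histone genes also cannot tell such recovery from a change in replication. Different recovery would be a property of the libraries that follows the groups. Changed processing or nuclear RNA content in CYGB-OE cells also stays open, as untested.

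Neighbouring genes may have changed together. Of 432 pairs of adjacent, non-overlapping called genes of the table within 100 kb, 73.1% changed in the same direction, against a mean of 59.0% over 10000 random assignments of the directions (two-sided test not run; one-sided permutation p = 0.0001, the smallest they can give). Among 242 pairs of protein-coding genes, 72.7% did, against 60.5% (one-sided permutation p = 0.0002). On chromosome 11, MMP10, MMP1, MMP3 and MMP12 lie in a row and all rose (log2 fold change 3.47 for MMP12), and on chromosome 2, IL1A, IL1B and IL37 all fell (-5.33 for IL37, or -6.02 without CYGB-OE replicate 1). This test does not tell causes apart, such as read-through between neighbours, shared regulation or clone differences between the groups, and none of these was tested.

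The G1/S list had 8 of 41 genes in the table and the G2/M list 0 of 44 (Fisher's exact test, two-sided p = 0.00199). These 2 lists were picked from 48 after their counts were seen, so this p decides nothing about a difference between replication and mitotic genes.

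Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 713 higher and 1749 lower genes, and 707 and 1749 at 2-fold or more; the highest of the other splits gave 0 in each case, so 1 of the 10 splits gave as many, in a table selected on the real split. For gene lists, the real split gave 3 past camera's threshold, the highest of the other splits gave 6, and 10 of the 10 splits gave 3 or more. The number of camera calls, those of the matrix protease, G1/S and histone lists, thus does not set the real split apart.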
